A study of Mus musculus with 12 samples.

How the data were processed

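Kidney RNA from 12 mouse samples was analysed, 3 in each of 4 groups, and each sample was assigned to its group and replicate by its title. The submitters' processing notes name the genome build mm10; the aligner, the quantification tool and its version are not given in the sources used here. The authors deposited 1 table of 19261 genes with estimated counts per library. These expected counts were not scaled: 76.8% to 78.8% of them were whole within 0.005, the others had decimals, and library totals differed. Beside them the authors deposited an expression value taken as FPKM from its scale, since its ratio to the count and the library total agreed between libraries within 0.458%. The table also holds group means, which were not used. Decimals in a count mean that reads fitting several transcripts were shared out, so that close paralogs (such as globins, Sprr2a genes and glutathione transferases) are uncertain. The table names no strandedness, so that overlapping and antisense genes are uncertain too. No gene encoded by the mitochondrial genome was among its rows, and the 971 gene models with only a BGIG identifier held 1.82% of the reads. Of 18290 Entrez identifiers 18164 matched the RefSeq annotation of GRCm38.p6, from which positions were taken, counted from 1.

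Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Library totals ranged from 13875942 to 15329347 and were scaled by trimmed means of M values. Genes were kept by edgeR's own expression filter, which left 14428. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, so that the groups share 1 estimate of the spread with 8 residual degrees of freedom, and each comparison was a contrast in it. The biological coefficient of variation was 26.8%. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, with 0.05 as the threshold. Levels are normalized CPM, given as mean and SD, and fold changes are given on the log2 scale with SE. Sums over a whole list are CPM scaled by the library total alone. Sums of the 13 adipose markers low in control are normalized CPM.

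Before the data were examined, 43 gene lists for kidney cell types, other tissues, RNA quality, stress and metabolism were fixed, of which 37 had at least 5 measured genes. Those not tested were mitochondrially encoded genes (0 measured), T and NK cells (3), neutrophils (3), adrenal gland (4), exocrine pancreas (1) and skeletal muscle (2). Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, from limma 3.58.1. Fry tests whether a list's genes move on balance in a single direction and does not compare them with other genes. For each list the calls were also adjusted over the list alone.

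The rule for named genes was also fixed before. It takes called genes whose groups do not overlap and whose higher mean is at least 1 CPM, up to 12 per direction, and the genes of lowest p up to 10 where fewer pass. It adds up to 4 members of each list past camera and 8 reference genes. The text names part of those genes. The busulfan genes in busulfan plus AOS against busulfan were named outside the rule.

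Alternatives were DESeq2 1.42.0, limma with voom and quality weights, limma on log2(FPKM + 1), relative log expression and upper quartile scaling, no filter on low counts, a filter at 5 CPM in 3 libraries, a replicate block, only the compared groups in the fit, each library left out in turn, a 2-fold minimum and an adjusted p of 0.1. The averaged comparisons and the setting without the adrenal and the hepatocyte library were chosen after the data were seen. Other splits of the libraries were counted, all 10 for 3 against 3 and 50 drawn for the interaction and the averaged comparisons.

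The procedure was tested on a single set of simulated data with 200 changed genes among 14293 genes and a further list of 30 shifted genes. It recovered 56.8% of 2-fold and 79.8% of 4-fold changes for busulfan against control, 60.0% and 78.8% for busulfan plus AOS against AOS, and 76.8% and 90.9% for the average busulfan effect, and with no change simulated for AOS against control it made 0 calls. In the same order, 8 of 153, 2 of 151 and 7 of 186 calls for busulfan were false. The least different pair of libraries, AOS replicates 1 and 2, differed by 5.36 times the sampling variance, so that no library was counted as a duplicate.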

Results

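RNA was sequenced from mouse kidney in 12 libraries that fall into 4 groups of 3. The control group is listed with neither treatment. The AOS group received alginate oligosaccharides, short sugar chains cut from the seaweed polymer alginate, at 10 mg/kg for 5 weeks. The busulfan group received busulfan, an alkylating drug that crosslinks DNA, once at 40 mg/kg. The last group received busulfan once and then AOS at 10 mg/kg for 5 weeks. The labels give each library as a separate sample but do not say that samples came from separate animals, so the p-values measure the spread between these samples. The labels write the strain as IRC and name the tissue as cells, while the title and the protocol name kidney. Library totals ranged from 13875942 to 15329347 estimated reads, and 14428 of 19261 genes had enough reads to be tested. A count of 0 in a library allows a level of up to 0.196 to 0.216 CPM (counts scaled by the library total), a limit that covers counting error only.

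The transcripts of the kidney tubule led every library. Kap, an androgen-regulated protein of the proximal tubule, held 2.06% to 4.42% of the reads, and the 35 proximal tubule markers together measured 67687.5 to 99213 CPM. The Y-linked gene Ddx3y was read in every library, at 63.5 CPM or more. Some libraries also carried transcripts of other tissues. The 14 adrenal markers summed to 11905 CPM in busulfan replicate 3 and to 56.8 to 69.6 CPM in the other 11 libraries, with Star, which carries cholesterol into mitochondria for steroid synthesis, at 2950.3 CPM. The 15 hepatocyte markers summed to 20974 CPM in replicate 3 of busulfan plus AOS, with Alb, serum albumin, at 10077 CPM, and to 137 to 1359.6 CPM elsewhere. The 15 adipose markers summed to 3070.3 and 3369 CPM in busulfan replicates 2 and 3, and to 1145 to 2003.5 CPM elsewhere. Pck1, a member that the proximal tubule expresses too, measured 965.8 to 2077.6 CPM over the 12 libraries. The 13 members low in control summed to 892 and 1549 CPM in busulfan replicates 2 and 3. Elsewhere they summed to 42.1 to 363 CPM, the highest in replicate 3 of busulfan plus AOS. In replicate 1 of busulfan plus AOS the immediate early gene Egr1 measured 327 CPM, against 1.38 to 30.2 CPM in the others. The groups were compared with all 12 libraries, and each count was repeated without the adrenal and the hepatocyte library, a setting chosen after these values were seen.

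**Figure D1:**
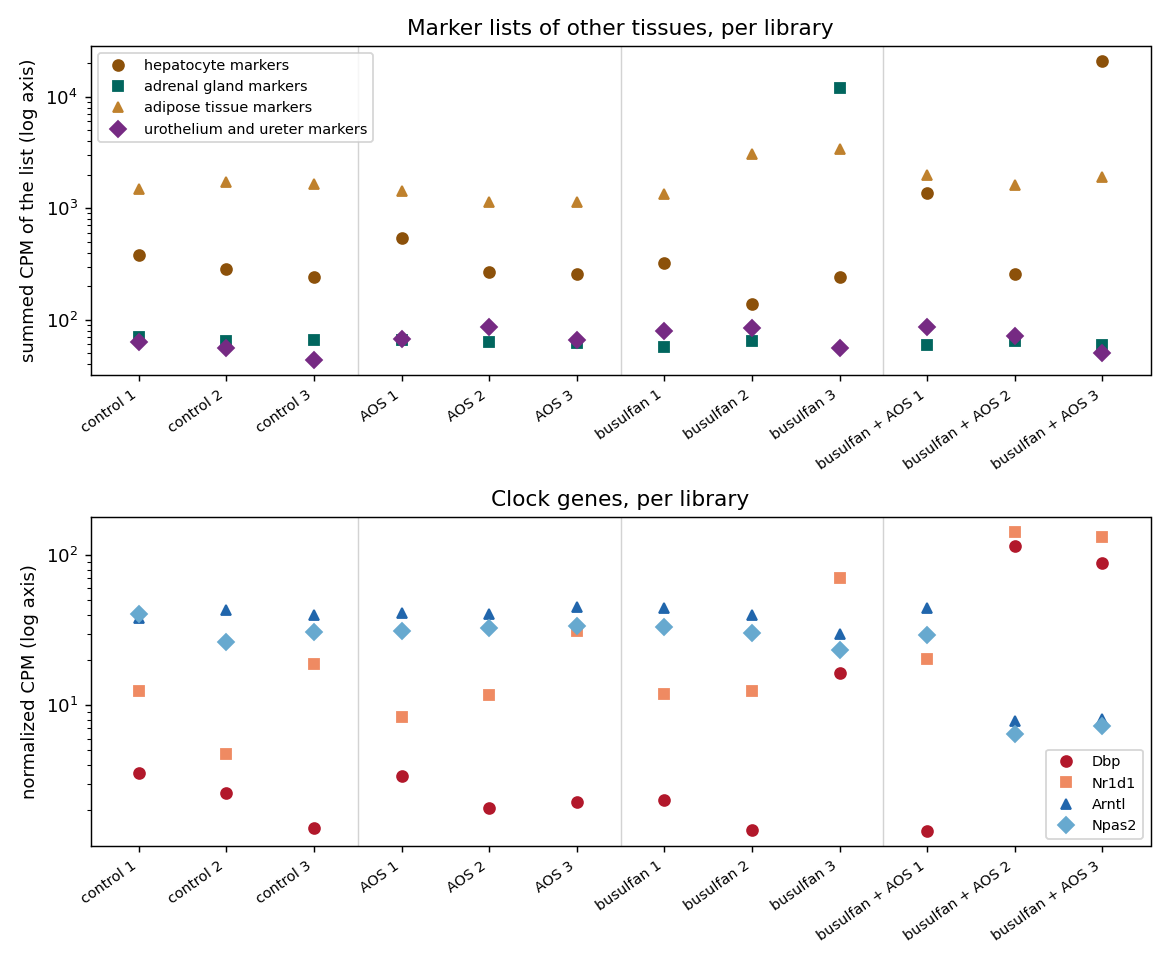
Summed CPM of 4 marker lists of other tissues (upper panel) and CPM of 4 clock genes (lower panel) for each of the 12 libraries, on log axes; each point is 1 library. The adrenal sum stands at 11905 CPM in busulfan replicate 3 and the hepatocyte sum at 20974 CPM in busulfan plus AOS replicate 3. The adipose sum includes Pck1, which the proximal tubule expresses too.

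Busulfan against control asks what the drug alone left in the kidney. Genes that the tumour suppressor p53 switches on after DNA damage were higher. Eda2r, a receptor of the tumour necrosis factor family, rose from 0.532 ± 0.181 to 8.52 ± 2.42 CPM (SD, n = 3 each), a log2 fold change of 3.98 ± 0.35 (SE). Phlda3, which restrains Akt signalling, rose by 3.52 ± 0.35, and Cdkn1a, the cell cycle inhibitor p21, by 2.69 ± 0.32, from 4.93 ± 1.14 to 31.8 ± 5.79 CPM. Ccng1, cyclin G, rose 2.18-fold with a log2 fold change of 1.12 ± 0.09, Exoc4, a subunit of the exocyst, by 0.81 ± 0.09, and Zmat3, an RNA-binding protein, by 0.79 ± 0.11. These 6 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at adjusted p of 0.00205 to 0.0485, and 0 fell. A further 4 genes of lowest p did not pass: Sprr2a1 at 5.19 ± 0.75 from 0 to 2 reads in control (7.90 without control replicate 2), Inka2 at 2.48 ± 0.37, Map3k20 at 1.13 ± 0.17 and Ddias at 2.12 ± 0.34, with adjusted p of 0.062 to 0.102. At an unadjusted p under 0.05 there were 1452 genes, against 721.4 by chance, and DESeq2 called 124, all 6 genes included. The count was 195 without busulfan replicate 1, 2 without control replicate 1, and 3 without control replicate 2 or without busulfan replicate 2. Of the 6 genes, 4 were among the 9 called without the adrenal and the hepatocyte library, where the adjusted p of Cdkn1a was 0.0529 and that of Zmat3 0.111. The calls of Ccng1 and Eda2r held with each of the 6 compared libraries left out, that of Phlda3 ended without control replicate 1, and those of Exoc4, Cdkn1a and Zmat3 each ended without control replicates 1 or 2 or busulfan replicate 2, the last 2 also without control replicate 3, and Zmat3 also without busulfan replicate 3. With only the 6 compared libraries in the fit, 0 genes passed. Of 16 alternative settings, Ccng1 and Eda2r passed in 15, Phlda3 in 14, Exoc4 in 12, Cdkn1a in 9 and Zmat3 in 5.

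The files name these genes by Entrez identifier, and the positions are those of the RefSeq annotation of the mouse assembly GRCm38.p6, named mm10 in genome browsers. Ccng1 (12450) lies on chromosome 11 from 40748552 to 40755309, Eda2r (245527) on chromosome X from 97333837 to 97377234, and Phlda3 (27280) on chromosome 1 from 135766085 to 135769134. Cdkn1a (12575) lies on chromosome 17 from 29090979 to 29100722, Exoc4 (20336) on chromosome 6 from 33249090 to 33973979, and Zmat3 (22401) on chromosome 3 from 32334792 to 32365665. All are protein-coding genes, and the values cover whole genes. The estimated counts of Cdkn1a were whole in 0% of the libraries, so the authors' counting shared some of its reads with other transcripts.

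**Figure D2:**
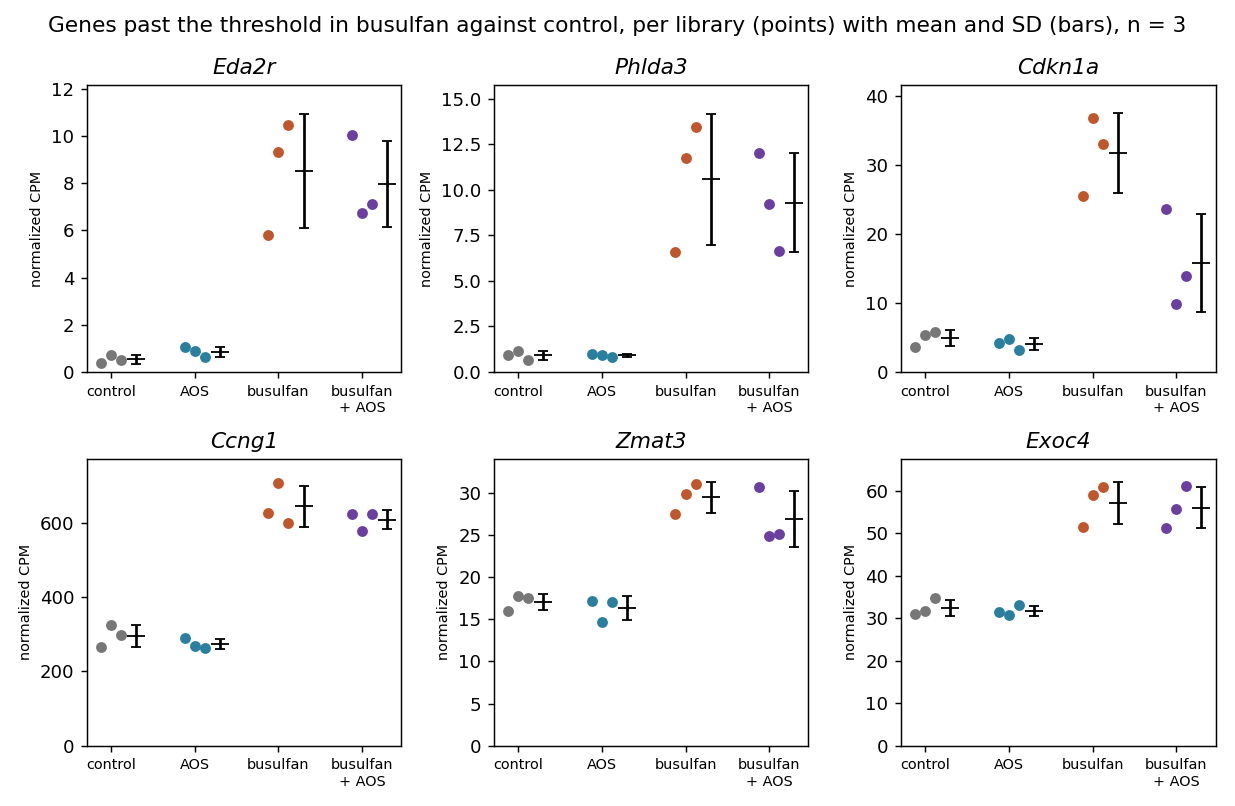
Normalized CPM of the 6 genes past the threshold in busulfan against control, for each library (points) with the mean and SD of each group (bars, n = 3). In all 6 panels the 6 libraries given busulfan lie above the 6 libraries without it.

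By gene group, p53 targets rose with busulfan: of 32 measured, 27 were higher, with a median log2 fold change of 0.73. Of them 5 were called over all genes and 18 rose when adjusted over the list alone. The call held with an estimated correlation (p = 4.73e-06). Mdm2, the ubiquitin ligase that p53 induces to limit itself, measured 0.44 ± 0.09 and the death receptor Tnfrsf10b 1.60 ± 0.30, neither past the threshold over all genes (adjusted p of 0.245 and 0.174). The 34 extracellular matrix genes were all higher, at a median of 1.12, and passed camera at its preset correlation; 0 were called over all genes and 25 when adjusted over the list alone, and p = 0.0666 with an estimated correlation. Among them, the gelatinase Mmp2 measured 2.10 ± 0.41, Col4a1, a basement membrane collagen, 0.58 ± 0.12, Postn 3.46 ± 0.73 and Col1a1 1.61 ± 0.46. Without busulfan replicate 3, which holds the adrenal transcripts, Postn measured 2.32 and Col1a1 0.88. The 16 fibroblast, pericyte and smooth muscle markers were all higher at a median of 1.02, with 13 called when adjusted over the list alone and 0 over all genes, and p = 0.0548 with an estimated correlation. Of 30 proliferation genes 29 were higher at a median of 0.92, 9 when adjusted over the list alone and 0 over all genes, with p = 0.0679 with an estimated correlation; the spindle genes Tpx2 and Prc1 measured 1.55 ± 0.28 and 1.75 ± 0.40, and Prc1 1.16 without busulfan replicate 2. Adipose markers moved with these groups, at a median of 4.01 (11 of 12 when adjusted over the list alone, p = 0.146 with an estimated correlation), with Fabp4 at 26.4 ± 7.35 CPM in control and 168 ± 136 CPM with busulfan. Summed matrix genes measured 1155, 1789 and 2972 CPM in the 3 busulfan libraries and 917 to 1166 CPM in control. Summed proliferation genes measured 119, 245 and 172 CPM in busulfan replicates 1, 2 and 3 and 114 to 117 CPM in control.

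Tubular injury markers were higher in 20 of 27 cases at a median of 0.49, 4 when adjusted over the list alone and 0 over all genes. With an estimated correlation p was 0.0052 before adjustment and did not pass after it, while fry gave an adjusted p of 0.0199. S100a6 measured 1.47 ± 0.31 and the keratin Krt19 2.01 ± 0.54 (2.83 without control replicate 1). Serpine2, a member of the complement and coagulation list, measured 1.54 ± 0.29. Of the reference genes for injury, Havcr1 measured 0.41 ± 0.27 and Lcn2 0.19 ± 0.55, and for tubule and renin Slc34a1, the phosphate transporter of the proximal tubule, measured -0.14 ± 0.14, Kap -0.45 ± 0.22 and Ren1 0.01 ± 0.17. Erythroid (blood) markers were lower, with negative values in 9 of 11 at a median of -0.90. Of them 1 was called when adjusted over the list alone and 0 over all genes (p = 0.0183 with an estimated correlation). Hbb-bs, a beta globin on this list, measured 0.29, 1.01 and 297 CPM in the control libraries. With busulfan it measured 0.69, 0 and 0.06 CPM. It also measured 140 CPM in AOS replicate 3 and 175 CPM in busulfan plus AOS replicate 1, so its high values did not follow the absence of busulfan. Hba-a1, an alpha globin with a near-identical copy that makes its count uncertain, measured -1.10 ± 0.29 and Alas2, the erythroid enzyme of haem synthesis, -1.02 ± 0.42. Urothelium markers measured a median of 2.25 over 7 genes (p = 0.0625 with an estimated correlation), with Upk1b at 2.29 ± 0.56. In all, 19 of 37 lists passed camera at the preset correlation, 1 with an estimated correlation and 2 by fry. The other 11 were interferon-stimulated genes (median 0.75, p = 0.194 with an estimated correlation), oxidative phosphorylation (-0.16, p = 0.161), male-biased genes (-0.31, p = 0.219), proximal tubule (-0.18, p = 0.259), loop of Henle (-0.24, p = 0.334), endothelium (0.25, p = 0.417), complement (0.78 and, without the adrenal and the hepatocyte library, 0.10, p = 0.334), apoptosis (0.11, p = 0.0494), endoplasmic reticulum stress (0.30, p = 0.444), immediate early genes (0.58, p = 0.421) and hepatocyte markers (-1.32, p = 0.48). Without the adrenal and the hepatocyte library 12 lists passed, and without busulfan replicate 3 alone 11; the matrix median was then 0.61 and that of the adipose list 3.03 in the first of these settings.

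Busulfan in animals that also received AOS shared Ccng1, Eda2r, Phlda3 and Exoc4 with busulfan against control. In busulfan plus AOS against AOS, Eda2r rose by 3.21 ± 0.33 on the log2 scale, from 0.856 ± 0.219 to 7.96 ± 1.81 CPM (SD, n = 3 each), Phlda3 by 3.32 ± 0.34, Ccng1 by 1.15 ± 0.09 and Exoc4 by 0.82 ± 0.09. Mgmt, the enzyme that removes alkyl groups from guanine in DNA, rose by 1.46 ± 0.18, from 3.52 ± 0.642 to 9.68 ± 1.05 CPM. Without AOS it was also higher with busulfan, at 8.35 to 9.72 CPM against 3.97 to 5.53 CPM in control, but was not called. The kinase Plk2 rose by 1.59 ± 0.21, the phospholipase Plcd4 by 2.29 ± 0.31, Inka2 by 2.71 ± 0.38 and Tpcn1, an ion channel of endosomes and lysosomes, by 0.74 ± 0.09. Its mean was low in the AOS group alone, at 96.6 CPM against 152 in control, 139.8 with busulfan and 162 with both, and AOS against control did not pass (adjusted p of 0.166). Asxl3, a chromatin regulator, fell by 0.99 ± 0.13. These 10 genes, 9 higher and 1 lower, passed in edgeR's quasi-likelihood test at adjusted p of 0.00164 to 0.0308, while Cdkn1a at 1.96 ± 0.32 had an adjusted p of 0.0734. Busulfan against control and this comparison share no library, and 4 genes were called in both (Ccng1, Eda2r, Phlda3 and Exoc4), where independent lists would share 0.00374. The lists are not independent, since 1 fit gave each gene the same estimate of the spread in both comparisons. A gene with a low estimate is favoured in both, so that 0.00374 may be too low. With only the compared groups in the fit, no gene passed in both. At an unadjusted p under 0.05 there were 1321 genes, and DESeq2 called 89 with all 10 among them. The count was 1 without AOS replicate 1, 2 or 3, namely Ccng1, 5 without busulfan plus AOS replicate 3, 25 without replicate 1 of that group, 4 with a replicate block, and 1 with only the compared groups in the fit. Inka2 lost its call without replicate 1, 2 or 3 of busulfan plus AOS, Plcd4 without replicate 1 or 3, and Tpcn1, Mgmt, Plk2 and Asxl3 without replicate 2 or 3. Without the adrenal and the hepatocyte library 6 genes passed, 5 of them shared; Tpcn1, Mgmt, Plk2, Plcd4 and Asxl3 then had adjusted p of 0.0645 to 0.105.

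**Figure D3:**
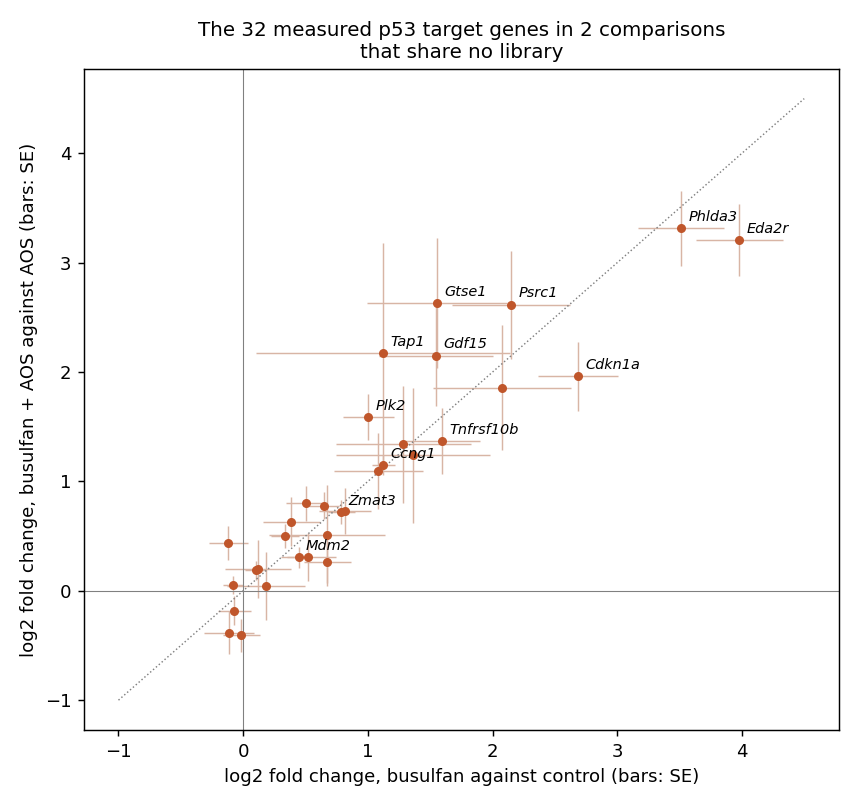
Log2 fold changes of the 32 measured p53 target genes for busulfan against control (horizontal axis) and busulfan plus AOS against AOS (vertical axis), with SE bars and a dotted line where both are equal; the comparisons share no library. Of the 32 genes 27 were above 0 on the horizontal and 29 on the vertical axis.

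The p53 targets rose here as well, 29 of 32 with a median of 0.76, 4 called over all genes and 20 higher and 1 lower when adjusted over the list alone (p = 3.14e-06 with an estimated correlation). Tnfrsf10b measured 1.37 ± 0.30 and Mdm2 0.30 ± 0.09, both short of the threshold over all genes. All 34 matrix genes were higher at a median of 0.61, with 0 called over all genes or when adjusted over the list alone and p = 0.132 with an estimated correlation; Mmp2 measured 1.63 ± 0.41 and Col4a2 0.34 ± 0.10. Proliferation genes measured a median of 0.77 (27 of 30 higher, p = 0.0919 with an estimated correlation), with Cdc20, which triggers anaphase, at 1.83 ± 0.44, and fibroblast markers 0.60 (16 of 16, p = 0.113). Cytokine and NF-kB response genes had a median of 0.40, 2 of 17 called when adjusted over the list alone and 0 over all genes, and p = 0.0114 with an estimated correlation, with Tnfaip3, a brake on NF-kB, at 0.60 ± 0.17. Ribosomal protein genes had a median of 0.12 (44 of 48, p = 0.0599 with an estimated correlation), glutathione genes 0.23 (p = 0.0382) and female-biased genes 0.61 (p = 0.0827). Hepatocyte markers stood at 4.87 (15 of 15 when adjusted over the list alone, p = 0.306 with an estimated correlation), and at -0.59 without the adrenal and the hepatocyte library. Their sum was 20974 CPM in busulfan plus AOS replicate 3 and 1359.6 and 258.9 CPM in replicates 1 and 2, while Apob (2.72 ± 0.63) measured 1120.6, 168 and 1031.5 CPM in replicates 1, 2 and 3. Immediate early genes stood at 1.22 (5 when adjusted over the list alone, p = 0.189 with an estimated correlation), with Egr1 at 4.23 ± 1.13 and at 1.93 without busulfan plus AOS replicate 1. Adipose markers measured a median of -0.28 here with 5 of 12 higher, while their sum was higher in busulfan plus AOS (2003.5, 1632 and 1911 CPM) than with AOS (1416, 1149 and 1145 CPM). Pck1, a member of the list which the proximal tubule expresses too, measured 1835, 1400.3 and 1568 normalized CPM against 1164, 965.8 and 1008.5 with AOS. Complement genes measured 0.85 (p = 0.165 with an estimated correlation) and 0.13 without the adrenal and the hepatocyte library; their sum was 1124.5, 1287 and 3030.8 CPM, the last in the hepatocyte library, against 1160 to 1192 CPM with AOS. The others past camera were oxidative phosphorylation (0.07, p = 0.496 with an estimated correlation), endoplasmic reticulum stress (0.30, p = 0.459), apoptosis (0.16, p = 0.0443), tubular injury (0.16, p = 0.0778), the renin axis (0.15, p = 0.0292), male-biased genes (-0.24, p = 0.363), intercalated cells (-0.16, p = 0.423), podocytes (0.27, p = 0.363) and urothelium (-0.68, p = 0.214). Summed endoplasmic reticulum stress genes measured 12092 CPM in replicate 1 of busulfan plus AOS and 6108 and 6233 CPM in replicates 2 and 3. With AOS alone they measured 7090 to 7716 CPM. In all 20 lists passed camera at the preset correlation, 17 without the adrenal and the hepatocyte library and 13 without busulfan plus AOS replicate 1, but 1, the p53 targets, with an estimated correlation and 1 by fry.

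Averaged over animals with and without AOS, a comparison of 6 libraries against 6 that was added after the values above were seen, busulfan raised 25 genes and lowered 3 in edgeR's quasi-likelihood test. Eda2r rose by 3.59 ± 0.24, Phlda3 by 3.42 ± 0.24, Ccng1 by 1.14 ± 0.06 and Cdkn1a by 2.32 ± 0.23, at adjusted p of 5.54e-05 to 0.00227. Ephx1, the microsomal epoxide hydrolase, rose 3.80-fold with a log2 fold change of 1.93 ± 0.25, Ddias by 2.10 ± 0.24, Inka2 by 2.60 ± 0.26, Plcd4 by 2.05 ± 0.22, and Dscaml1, a cell adhesion molecule, by 4.46 ± 0.55, from 0 to 2 reads in the libraries without busulfan to 12 to 22 reads with it (a log2 fold change of 5.40 without AOS replicate 1). The death receptor Tnfrsf10b rose by 1.48 ± 0.21, Serpine2 by 1.43 ± 0.21 and Mmp2 by 1.86 ± 0.29. The mitotic genes Psrc1, Ckap2l and Tpx2 rose by 2.38 ± 0.34, 1.55 ± 0.24 and 1.23 ± 0.19. Asxl3 fell by 0.70 ± 0.09, and the adjusted p of Mdm2 (0.37 ± 0.07) was 0.0727. At an unadjusted p under 0.05 there were 1751 genes, and DESeq2 called 223 and voom with quality weights 60. The count was 163 without busulfan replicate 1 and 18 without AOS replicate 1; without the adrenal and the hepatocyte library it was 24, of which 18 were shared. Mmp2, Serpine2, Tnfrsf10b, Psrc1, Ckap2l, Tpx2 and Asxl3 were not among the 18, at adjusted p of 0.0557 to 0.0912. Mmp2 also lost its call without each library except busulfan replicates 1 and 3, with adjusted p of up to 0.153, Tpx2 without each except busulfan replicates 1, 2 and 3 (up to 0.146), and Ephx1 without control replicates 2 or 3 or AOS replicate 1 (up to 0.0569). Tnfrsf10b lost its call without control replicate 1, 2 or 3, AOS replicate 2 or busulfan replicate 2 (up to 0.0857), and Asxl3 without AOS replicate 1 (0.0586). Psrc1 did so without control replicate 1, 2 or 3, AOS replicate 1 or 3, busulfan replicate 2 or busulfan plus AOS replicate 1 or 2 (up to 0.104), and Ckap2l without these or without busulfan plus AOS replicate 3 (up to 0.116). Serpine2 did so without control replicate 1 or 3, AOS replicate 1 or 2, busulfan replicate 2 or busulfan plus AOS replicate 1 or 3 (up to 0.104). Ccng1, Eda2r, Phlda3, Cdkn1a, Inka2, Plcd4, Ddias and Dscaml1 passed in every setting that gave them a value.

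Over the same 6 against 6 libraries, 28 of 32 p53 targets were higher at a median of 0.73, 9 called over all genes and 22 when adjusted over the list alone (p = 1.6e-06 with an estimated correlation). All 34 matrix genes were higher at a median of 0.91, 1 called over all genes and 30 when adjusted over the list alone (p = 0.0485 with an estimated correlation). Fibroblast markers had a median of 0.79, 0 called over all genes and 14 of 16 when adjusted over the list alone (p = 0.0377), and proliferation genes 0.94, 1 over all genes and 17 of 30 when adjusted over the list alone (p = 0.0416 with an estimated correlation). Erythroid markers stood at -0.76 (1 of 11 lower when adjusted over the list alone, p = 0.0241 with an estimated correlation). Tubular injury markers measured 0.60 (p = 0.00325 with an estimated correlation) and apoptosis genes 0.15 (7 when adjusted over the list alone, p = 0.0221), while immediate early genes stood at 1.24 and adipose markers at 2.12. The injury genes summed to 4024 CPM in replicate 3 of busulfan plus AOS, the hepatocyte library, and their member Fgb is also a hepatocyte marker. They summed to 1286 to 1541 CPM in the other libraries given busulfan and to 942 to 1198 CPM in those without it. Summed immediate early genes measured 854 CPM in busulfan replicate 3 and 1279 CPM in replicate 1 of busulfan plus AOS. In the other libraries they measured 189 to 354 CPM. The p-values with an estimated correlation given here are before adjustment. Of 18 lists past camera at its preset correlation, 1, the p53 targets, held after adjustment with an estimated correlation, and 9 lists passed by fry. A further 7 lists passed camera in no comparison. For busulfan on average these were crosslink repair genes of the Fanconi pathway (median -0.03 over 25), NRF2 antioxidant genes (0.01 over 26), cytochrome P450 genes (0.03 over 30), fatty acid oxidation (-0.02 over 34), cholesterol synthesis (0.05 over 32), macrophage markers (0.26 over 21) and clock genes (0.28 over 20), at adjusted p of 0.135 to 0.991 by camera. By fry the clock list had an adjusted p of 0.036 here and 0.0221 in busulfan plus AOS against control, and 0.162 and 0.0521 without the adrenal and the hepatocyte library. Its summed genes measured 1551 and 1255 CPM in replicates 2 and 3 of busulfan plus AOS and 883 to 1084 CPM in the other libraries.

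AOS against control asks what the oligosaccharides did without the drug, and 0 genes passed in edgeR's quasi-likelihood test. The lowest adjusted p was 0.166, shared by Rsbn1, at -1.96 ± 0.27 on the log2 scale, and Tpcn1 at -0.65 ± 0.09, which measured 152 ± 15.4 CPM in control and 96.6 ± 5.36 CPM with AOS (SD, n = 3 each). The next genes by p, at an adjusted p of 1, were Mien1 (-0.34 ± 0.06), Metrnl (-0.76 ± 0.14), Fn3krp (-0.77 ± 0.15), Rgl2 (1.81 ± 0.36), Slc18a1 (-0.96 ± 0.20), Cda (-0.55 ± 0.12), Pik3r1 (0.31 ± 0.07) and Hexdc (-0.72 ± 0.16). The reference genes Cdkn1a (-0.28 ± 0.32), Mdm2 (0.08 ± 0.09), Lcn2 (0.35 ± 0.55), Ren1 (0.07 ± 0.17), Kap (-0.30 ± 0.22), Slc34a1 (-0.16 ± 0.14) and Hba-a1 (-0.19 ± 0.28) also did not pass, nor did Havcr1 at 0.77 ± 0.27. At an unadjusted p under 0.05 there were 518 genes, fewer than the 721.4 given by chance. DESeq2 called 10 genes and voom with quality weights 1, and limma on log2(FPKM + 1) 0. The counts of Rsbn1 were whole in 0% of the libraries, so they hold shared reads.

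By group, 9 lists passed camera at the preset correlation for AOS against control, 0 with an estimated correlation after adjustment and 0 by fry. B cell and plasma cell markers had a median of 0.33 over 7 genes, 1 higher when adjusted over the list alone and 0 over all genes (p = 0.0107 with an estimated correlation); the B cell receptor subunit Cd79a measured 1.53 ± 0.45 and Jchain, the joining chain of secreted antibodies, 1.36 ± 0.48 and 2.14 without control replicate 2. Interferon-stimulated genes had a median of 0.52 with 31 of 32 higher (p = 0.213 with an estimated correlation), with Ifit3 at 1.20 ± 0.38. Intercalated cell markers measured 0.26 (p = 0.0922 with an estimated correlation), with the chloride exchanger Slc26a4 at 0.41 ± 0.15, and principal cell markers 0.15 (p = 0.321). Tubular injury markers measured 0.20 (p = 0.0209 with an estimated correlation) and urothelium markers 0.75 (p = 0.105), and proximal tubule markers -0.08 (p = 0.358). Oxidative phosphorylation genes had a median of -0.14 with 39 of 40 lower (p = 0.117 with an estimated correlation) and ribosomal protein genes -0.10 with 42 of 48 lower (p = 0.0544); Atp5g1 measured -1.19 ± 0.37, from counts whole in 0% of the libraries, and Rps27 -0.27 ± 0.08.

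Busulfan plus AOS against busulfan asks whether AOS changed the kidney after the drug. In edgeR's quasi-likelihood test 0 genes passed, at a lowest adjusted p of 0.477. The 10 genes of lowest p were Sprr2a1, a proline-rich protein of squamous epithelium (-3.79 ± 0.64), Smtnl2 (1.05 ± 0.18), Tgoln1 (-0.66 ± 0.11), Mcoln2 (1.92 ± 0.35), Gstt2 (0.81 ± 0.15), Col20a1 (-0.64 ± 0.12), Ggt6 (1.22 ± 0.23), Apob (3.42 ± 0.65, and 4.10 without busulfan replicate 1), Hnmt (0.50 ± 0.10) and Klhl21 (0.51 ± 0.10). The reads of Sprr2a1 and Gstt2 may be split with close paralogs by the authors' counting, which makes both uncertain. Counts at an unadjusted p under 0.05 came to 1254, against 721.4 by chance, and DESeq2 called 24 genes and voom with quality weights 0. The count was 26 without busulfan plus AOS replicate 1, 3 without busulfan replicate 1, and 1 without busulfan replicate 3.

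The 6 genes raised by busulfan were named in this comparison because of that call and not by the rule for named genes, except Cdkn1a. Cdkn1a measured 31.8 ± 5.79 CPM with busulfan and 15.9 ± 7.07 CPM with busulfan plus AOS, a ratio of 0.499 with an SE of 0.30 on the log2 scale and an adjusted p of 0.477. Its libraries read 25.5, 36.9 and 33.1 CPM with busulfan and 23.7, 9.91 and 13.98 CPM with busulfan plus AOS. The other 5 lay closer to 0: Ccng1 -0.08 ± 0.09, Eda2r -0.10 ± 0.29, Phlda3 -0.19 ± 0.30, Exoc4 -0.03 ± 0.09 and Zmat3 -0.13 ± 0.11. All 6 had a sign opposite to the busulfan effect. Both comparisons use the same busulfan libraries, and simulated groups with no AOS effect gave 56.0% opposite signs. Eda2r, Phlda3 and Exoc4 turned positive without busulfan replicate 3 (0.08, 0.02 and 0.02), Eda2r also without busulfan plus AOS replicate 2 (0.01) and Exoc4 without replicate 1 of that group (0.03). Of the 6, 0 moved back past the threshold and 4 were still called against control. Of the genes each setting called for busulfan, 7 moved back by DESeq2, 3 without busulfan replicate 1 and 1 without busulfan replicate 3.

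Among gene groups, 13 lists passed camera at the preset correlation, 0 with an estimated correlation after adjustment and 1 by fry, the renin, erythropoietin and vitamin D axis. That list had a median of 0.15 with 13 of 15 higher, 1 when adjusted over the list alone and 0 over all genes (p = 0.0026 with an estimated correlation); the oxygen sensor Egln3 measured 0.99 ± 0.25 and Ren1 0.40 ± 0.17. B cell markers measured 0.80 (1 when adjusted over the list alone, p = 0.00832 with an estimated correlation), with Cd79b at 1.92 ± 0.50, cytokine and NF-kB genes 0.28 (p = 0.0405), with Tnfaip3 at 0.66 ± 0.17, and glutathione genes 0.15 (p = 0.0445). Hepatocyte markers stood at a median of 6.09 (p = 0.134 with an estimated correlation), with Alb at 6.74 ± 2.03 and at 0.62 without busulfan plus AOS replicate 3, and adipose markers at -3.45 (p = 0.186), with Fabp4 at -2.76 ± 0.69 and at -1.91 without the adrenal and the hepatocyte library. Urothelium markers measured -1.99 (p = 0.0685 with an estimated correlation), with Upk1b at -2.33 ± 0.56 (-3.01 without busulfan plus AOS replicate 1), and loop of Henle markers 0.59 (p = 0.163). The other lists were oxidative phosphorylation (0.07, p = 0.398 with an estimated correlation), principal cells (0.22, p = 0.222), proximal tubule (0.10, p = 0.35), intercalated cells (0.15, p = 0.417) and erythroid markers (0.32, p = 0.095). Reference genes did not pass: Havcr1 measured 0.28 ± 0.27, Lcn2 0.78 ± 0.53, Kap 0.16 ± 0.22, Mdm2 -0.06 ± 0.09, Slc34a1 0.09 ± 0.14 and Hba-a1 0.42 ± 0.28. Without busulfan replicate 3 the number of lists was 20.

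Busulfan plus AOS against control again raised p53 targets. Eda2r rose by 3.88 ± 0.35, Phlda3 by 3.33 ± 0.34, Ccng1 by 1.04 ± 0.09, Exoc4 by 0.79 ± 0.09, Plk2 by 1.55 ± 0.21 and Ddias 5.67-fold with an SE of 0.34 on the log2 scale. These were the 6 genes past the threshold in edgeR's quasi-likelihood test (n = 3 each, adjusted p of 0.00262 to 0.0448), and 0 fell. Piezo1, a mechanically gated channel, measured 0.72 ± 0.10 at an adjusted p of 0.0504, Inka2 2.49 ± 0.37, Plcd4 1.92 ± 0.31, Asxl3 -0.88 ± 0.13, Mdm2 0.38 ± 0.09 and Cdkn1a 1.68 ± 0.31 (adjusted p of 0.188). Of the 6 genes, 4 were also called in busulfan against control; the comparisons share the control libraries, for which simulated unchanged groups shared 0.025 calls on average and 1 at most, and independent lists would share 0.0025. Part of that overlap may come from the shared controls and the shared estimate of the spread. At an unadjusted p under 0.05 there were 1442 genes, and DESeq2 called 90. The count was 2 without control replicate 1, leaving Ccng1 and Eda2r, and 25 without busulfan plus AOS replicate 1. Plk2 and Ddias lost their calls without control replicate 1 or 3 or busulfan plus AOS replicate 2 or 3 and without the adrenal and the hepatocyte library (adjusted p of 0.108 each), Ddias also without control replicate 2, and Exoc4 without control replicate 1 or 2 or busulfan plus AOS replicate 2 or 3.

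In this comparison 30 of 32 p53 targets were higher at a median of 0.73, 4 called over all genes and 19 when adjusted over the list alone (p = 3.18e-06 with an estimated correlation). Bbc3, the cell death protein PUMA, measured 1.51 ± 0.36. Tubular injury markers were higher in 25 of 27 cases, at a median of 0.53 and with 0 called over all genes or when adjusted over the list alone; this was the other list to hold with an estimated correlation (adjusted p = 0.0434), and without the adrenal and the hepatocyte library it did not, at p = 0.0372 before adjustment. Krt18 measured 1.13 ± 0.28. Matrix genes had a median of 0.80 (2 when adjusted over the list alone, p = 0.114 with an estimated correlation), with Mmp2 at 1.68 ± 0.41, fibroblast markers 0.77 (p = 0.0879) and proliferation genes 0.83 (p = 0.133). Cytokine genes stood at 0.32 (p = 0.0137 with an estimated correlation), with Tnfaip3 at 0.85 ± 0.17, and apoptosis genes at 0.33 (5 when adjusted over the list alone, p = 0.0164). Hepatocyte markers measured 4.82 (p = 0.383 with an estimated correlation), immediate early genes 1.36 (p = 0.169), with Egr1 at 4.74 ± 1.17 and at 2.44 without busulfan plus AOS replicate 1, and complement genes 0.93 (p = 0.124). Without the adrenal and the hepatocyte library complement genes stood at 0.24 and hepatocyte markers at -0.58. Male-biased genes measured -0.32 (p = 0.179 with an estimated correlation), with Odc1, ornithine decarboxylase, at -1.07 ± 0.33 from counts whole in 0% of the libraries. In all 17 lists passed camera at the preset correlation, 2 with an estimated correlation and 5 by fry.

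The difference between the AOS effect after busulfan and the AOS effect alone was tested as an interaction, and 0 genes passed in edgeR's quasi-likelihood test, at a lowest adjusted p of 0.292. Sprr2a1 measured -7.26 ± 1.02, Tpcn1 0.86 ± 0.13, Sptssb -8.56 ± 1.44, Rsbn1 1.80 ± 0.37, Il15ra 0.96 ± 0.20, Psca -5.61 ± 1.23, Egln3 1.21 ± 0.36 and Cdkn1a -0.73 ± 0.44. Sprr2a1 and Sptssb were near the floor in control, at means of 0.0482 and 0.0485 CPM, so that the fitted size is not a bound. Without control replicate 2 Sprr2a1 measured -9.98, without control replicate 1 Sptssb -11.28, and without busulfan plus AOS replicate 1 Psca -6.74; Sptssb measured -7.45 without busulfan replicate 2. At an unadjusted p under 0.05 there were 850 genes, against 721.4 by chance, DESeq2 called 11 and voom with quality weights 0. Without busulfan plus AOS replicate 1 the count was 1. Averaged over animals with and without busulfan, a comparison also added after the values were seen, AOS gave 0 genes in edgeR, 832 at an unadjusted p under 0.05, 21 by DESeq2 and 0 by voom with quality weights. The lowest p values were those of Mcoln2 (1.41 ± 0.24), Rsbn1 (-1.06 ± 0.19), Pxdn (-0.51 ± 0.09), Cpb2 (3.32 ± 0.63, and 2.64 without the adrenal and the hepatocyte library), Rgl2 (1.25 ± 0.24) and Ggt6 (0.84 ± 0.16), at an adjusted p of 0.634. The count was 1 without busulfan replicate 3 and 2 without busulfan plus AOS replicate 1. Of 12 lists past camera for the average AOS effect, 0 held with an estimated correlation after adjustment and 1 passed by fry, the B cell and plasma cell markers, with all 7 genes higher at a median of 0.61 and 3 called when adjusted over the list alone (p = 0.00188 with an estimated correlation). Without busulfan replicate 3 the number of lists was 26. The genes' AOS effects with and without busulfan, which share no library, had a Spearman correlation across genes of -0.0211 and those of busulfan with and without AOS one of 0.197 (Pearson 0.0433); genes are not independent replicates.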

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

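The tests of treatment and of a wrong label for the liver and adrenal genes and all tests for the matrix genes were chosen after the results were seen, as was the setting without the adrenal and the hepatocyte library. The averaged comparisons, and so their splits, were also chosen after. The tests on liver and adrenal genes outside the fixed lists and the splits of the planned comparisons were chosen before.

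The AOS effect with busulfan minus the AOS effect without it set 11 gene lists apart from the other genes by camera at its preset correlation, which is why they are listed here. The median log2 differences were 0.318 for cytokine and NF-kB genes, -0.764 for interferon-stimulated genes, 0.281 for glutathione genes, 0.221 for oxidative phosphorylation, 0.108 for ribosomal protein genes, 0.210 for the renin axis, 0.170 for proximal tubule markers, 0.190 for podocyte markers, -3.99 for adipose, 6.41 for hepatocyte and -2.73 for urothelium markers. With an estimated correlation and adjustment 0 of them passed, and fry, which tests a list against no change, passed 0 (adjusted p of 0.150 to 0.832). Of single p with an estimated correlation, the renin axis had 0.00715, urothelium 0.0303 and glutathione genes 0.0363. Without the adrenal and the hepatocyte library the hepatocyte median was 0.336 and the proximal tubule median 0.0441, and camera called neither. The adipose list was not called there either, at a median of -3.64. Camera called the other lists there. Medians were larger in size for cytokine (0.331), interferon-stimulated (-0.826), ribosomal protein (0.173), podocyte (0.445) and urothelium genes (-3.89). They were smaller for glutathione genes (0.118), oxidative phosphorylation (0.136) and the renin axis (0.127).

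Hepatocyte genes stood high in busulfan plus AOS replicate 3 and adrenal genes in busulfan replicate 3. Of 23 liver genes outside the fixed list 22 were highest in the first library, and of 12 adrenal genes 12 were highest in the second. An effect of treatment on the whole group is argued against: the other libraries of each group had median log2 ratios to control of -0.527 for hepatocyte and 0.160 for adrenal markers. A liver or an adrenal sample under a kidney label is argued against as well, since proximal tubule markers stood at 94.2% and 76.2% of the median of the other libraries. RNA of adjoining liver and adrenal tissue may have entered these samples, and the tests do not say at which step.

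Matrix, fibroblast and proliferation genes were higher with busulfan. Liver and adrenal RNA cannot be the whole cause, since the matrix median was 0.633 without those libraries and 0.912 with them. The matrix list's p with an estimated correlation rose from 0.0485 to 0.056, both before adjustment. After adjustment the list did not pass in either setting. A lower share of tubule RNA is argued against as the whole cause. The fibroblast score rose by 0.559 more than the mean of the endothelial, podocyte and macrophage scores (two-sided exact permutation p = 0.00216, the smallest that 924 splits allow). The splits did not keep the AOS groups apart. Adipose or adrenal RNA in busulfan replicates 2 and 3 may also have raised the fibroblast score, so the test cannot exclude a lower tubule share as part of the cause. Adipose RNA may account for part or all of the matrix difference in animals without AOS. The adipose median was 4.01 there, beside a matrix median of 1.12. In busulfan replicate 1 the 13 adipose markers low in control summed to 49.4 CPM, and the matrix genes to 1155 CPM. Both lay within the range of control, 49.3 to 101.9 CPM and 917 to 1166 CPM. In animals given AOS adipose RNA is argued against as the whole cause: 13 adipose markers low in control rose by 74.8 CPM with busulfan (SE 104; per library -50.1, 9.30 and 265 CPM, the last in the hepatocyte library, where Car3, also a liver gene, held 290 of 363 CPM), where the matrix rise of 489 CPM would need 371 CPM at the lowest ratio in busulfan replicates 2 and 3; an effect of busulfan on the kidney stays open in both.

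Chance is argued against for the average busulfan effect, but not excluded, since the comparison was chosen after the data were seen. There 28 genes passed, and of 50 splits of the libraries 1, the real one, gave as many, with 1 gene in the highest other. For the interaction (0 genes, highest other 1) and the average AOS effect (0 genes, highest other 11) a count of 0 is reached by all 50 splits whatever the data, so these counts decide nothing about chance. The split with 11 genes points to a structure of the samples; what separates them was not tested. For groups of 3 the 10 splits are too few for a share under 0.05. The real values and the highest others were 6 and 2 for busulfan against control, 0 and 1 for AOS against control, 0 and 5 for busulfan plus AOS against busulfan, 10 and 0 for busulfan plus AOS against AOS, and 6 and 1 for busulfan plus AOS against control. The Spearman correlation of the busulfan effects, 0.197, was reached by 3 of 50 splits, with 0.241 the highest other.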

How the results depend on the processing

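The setting without the adrenal and the hepatocyte library and the averaged comparisons were chosen after the data were seen. Counts of genes are given in the order busulfan against control, AOS against control, busulfan plus AOS against busulfan, against AOS and against control, interaction, average busulfan and average AOS effect. DESeq2 called 124, 10, 24, 89, 90, 11, 223 and 21 genes. Voom with quality weights called 1 for AOS against control, 29 and 10 for busulfan plus AOS against AOS and control, and 60 for the average busulfan effect. With only the compared groups in the fit the counts against control were 0 for busulfan and 0 for busulfan plus AOS, and 1 against AOS, with fewer samples to estimate the spread. At an adjusted p of 0.1 there were 10 for busulfan against control, 21 for busulfan plus AOS against AOS and 56 for the average. Without the adrenal and the hepatocyte library there were 1 for busulfan plus AOS against busulfan and 6 against AOS. Leaving out each library gave 2 to 195, 0 to 0, 0 to 26, 1 to 25, 2 to 25, 0 to 1, 18 to 163 and 0 to 2. Lists past camera numbered 12 for busulfan against control without the adrenal and the hepatocyte library. With an estimated correlation they numbered 1, 0, 0, 1, 2, 0, 1 and 0, and by fry 2, 0, 1, 1, 5, 0, 9 and 1. Leaving out each library gave 11 to 23, 7 to 12, 11 to 20, 13 to 19, 14 to 21, 10 to 16, 16 to 22 and 10 to 26 lists. Genes that moved back numbered 7 by DESeq2, 1 without the adrenal and the hepatocyte library, and 0 to 3 with each library left out. The Spearman correlation across genes of the busulfan effect without AOS against busulfan effect with AOS was 0.129 without both libraries and 0.0754 to 0.249 with each left out. That of the AOS effect without busulfan against AOS effect with busulfan reversed to 0.131 and ranged from -0.0910 to 0.135, with reversals without control replicate 1 (0.0309) and busulfan replicate 3. Uncalled genes changed sign. With each library left out, Lcn2 ranged from -0.142 to 0.639 and Ren1 from -0.143 to 0.171 for busulfan against control (-0.0760 without both libraries), and Ren1 from -0.0832 to 0.230 for AOS against control. For busulfan plus AOS against busulfan the values were 0.152 for Eda2r, 0.216 for Phlda3, -0.0231 for Havcr1, -0.0806 for Kap and 0.0036 for Mdm2 without both libraries. With each left out Eda2r ranged from -0.308 to 0.0772, Phlda3 from -0.438 to 0.0216, Exoc4 from -0.0997 to 0.0261, Kap from -0.0842 to 0.369 and Mdm2 from -0.177 to 0.0226. Of 163 named pairs of gene and comparison, leaving out a library kept sign and side of the threshold in 1060 cases, lost a call in 119 and gained 25. For these changes the cause was not tested. The replicate numbers were not used as pairs in the main fit. Of 18 pairs with the same number 4 correlated over 0.1, at most 0.159, and 6 of 12 libraries correlated best with their own number. These values do not settle whether the samples are paired. A replicate block gave 5, 0, 0, 4, 5, 0, 24 and 0 genes and 20, 11, 16, 20, 15, 12, 19 and 13 lists. Another pseudocount and quantile scaling were not run because the table holds counts. Low counts limit genes near the floor.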

Other observations

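The test of the clock genes below was chosen before the values of its 9 genes were examined, but for libraries picked because other clock genes stood apart in them.

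Clock genes stood apart in replicates 2 and 3 of busulfan plus AOS. Dbp, a clock output gene, measured 114 and 89.0 CPM there and 1.45 to 16.5 CPM in the other libraries, and Nr1d1, which represses Arntl, measured 142 and 132 CPM against 4.70 to 70.0 CPM. Arntl measured 7.86 and 8.15 CPM there, and 29.9 to 45.2 CPM elsewhere. Busulfan replicate 3 leaned the same way, with the 16.5 CPM of Dbp, the 70.0 CPM of Nr1d1 and the 29.9 CPM of Arntl (Dbp at most 3.56 CPM and Nr1d1 at most 31.2 CPM in the 9 left), but not for Tef and Hlf. Of 9 further clock genes 8 lay beyond the range of the other 10 libraries in both libraries in the direction predicted for another phase of the daily clock, and Usp2 did not. These samples may have been taken at another time of day; whether the time of collection or the treatment set the phase was not tested, and comparisons with the busulfan plus AOS or the busulfan group hold any such difference. Cdkn1a measured 9.91 and 13.98 CPM in replicates 2 and 3 of busulfan plus AOS and 23.7 CPM in replicate 1.

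The beta globin gene Hbb-bs measured 297 CPM in control replicate 3, 140 CPM in AOS replicate 3 and 175 CPM in busulfan plus AOS replicate 1, and 0 to 11.3 CPM in the other libraries. Hbb-bt, another beta globin, was high in the same libraries, at 58.0, 26.8 and 31.4 CPM, and measured 0 to 2.62 CPM in the others. These libraries come from groups with and without busulfan, and the cause of the pattern was not tested.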
